A study of Homo sapiens and Mus musculus with 52 samples.

How the data were processed

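RNA was measured by sequencing in 52 libraries of established cancer cell lines, in 26 groups of 2 biological replicates per the labels. Of these, 32 libraries made 16 human groups, with HGC27, OE21, OE33 and CAL27 each in WT and N173S cells under PBS or IFNB, and 20 made 10 B16F10 mouse groups, with 5 genotypes under PBS or IFNb. The group of each library was taken from its label, and the meaning of the numbers inside the titles was not given in the sources used here. Doses and times of treatment were not given there either. Per the labels' protocols, total RNA was extracted with a Qiagen column kit, mRNA was selected by its poly-A tail, and an Illumina HiSeq4000 read both ends of each fragment. The labels also name an amplicon library kit, which was not resolved against the poly-A protocol.

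The authors deposited 1 raw count per gene and library, with no normalization. Per the submitters' processing notes, the tools were STAR, featureCounts and DESeq2 and the builds mm10, GRCh38 and GRCm38. Their versions, the order of steps, the strand setting and the treatment of reads that map to several places were not given in the sources used here. The deposited counts were whole numbers for 61806 human and 56691 mouse gene IDs, and 20417 and 2639 of these carried no symbol in the files. Of the human IDs, 58217 were found in GENCODE v29 on GRCh38, 58204 of them overlapping the same place and 41628 with the same start and end. Human coordinates were therefore read as GRCh38, and no mouse coordinate was used, since the build of the mouse columns could not be settled. Genes with near-identical copies, and antisense genes where strand is unknown, were treated as uncertain.

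Gene tests were run with edgeR 4.0.16 under R 4.3.3 on the deposited counts. Genes were kept by filterByExpr with a minimum count of 10, libraries were scaled by TMM, and the robust quasi-likelihood F test was applied to 1 mean per group. Benjamini-Hochberg adjustment ran over the genes tested in each of 43 contrasts, and a gene was called at an adjusted p of 0.05. Each human line was fitted with its own 8 libraries, the average over the 4 lines with all 32, and B16F10 with all 20. Each line gave 5 contrasts, 20 in all: N173S against WT under PBS and under IFNB, IFNB against PBS in each genotype, and the difference in response. The average took the same 5. B16F10 gave 18: IFNb in 5 genotypes, 5 genotype contrasts in each treatment and 3 differences in response. In the average, the spread is that between libraries of 1 line and not between lines. limma 3.58.1 was also run on the 4 per-line changes, which takes lines as replicates.

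Standard errors are those of the edgeR coefficients, from the quasi-likelihood statistic. CPM values use the TMM-scaled library size and are given as mean and SD over 2 libraries. Where a group had no counts of a gene, the fold was computed against a floor of 3 counts over the group, and with 1 to 3 counts a 95% counting interval was computed. List medians were also computed with genes at 0 counts at that bound.

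Before the data were examined, 15 gene lists were fixed for each species: interferon-stimulated genes; nucleic acid sensors; interferons, cytokines and chemokines; MHC class I antigen presentation; immune checkpoint ligands and MHC class II; cell death; integrated stress response; NF-κB targets; cell cycle and DNA replication; epithelial and squamous differentiation; mesenchymal genes; melanocyte lineage; immune cell markers; fibroblast and endothelial markers; and the ADAR family. Lists with at least 5 tested members were tested with camera in limma, with a preset correlation of 0.01 between genes, a prior count of 2 and adjustment over the lists of a contrast. The same test with an estimated correlation was an alternative. Of 260 list calls, 176 held with it and 84 did not. A few further lists were chosen after the results were seen and are used in the closing observations and in 1 figure panel.

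The rule for named genes was also fixed then. ADAR or Adar comes first. For each genotype contrast and response difference, and for the response of WT cells, it takes the 4 called genes with the highest and the 4 with the lowest change that have a symbol, a mean log2 CPM of at least 1 over the libraries compared and libraries that do not overlap between the groups, and for the average 6 each way with the same sign in all 4 lines. For the average the overlap was read within each line, and for a difference in response over all differences between IFN and PBS libraries. From each list described it takes up to 2 called members each way, and further members may be given. Of the genes it took, those that lost their call without 1 library, or rested on few counts, were often left out. A gene named outside the rule is said to have been chosen after its values were seen. Some genes that the rule took are not reported here, nor are Y-linked genes and XIST.

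The alternatives were DESeq2 1.42.0 in place of edgeR, DESeq2 size factors in place of TMM, no filter, a minimum count of 50, the replicate number as a block, each library left out in turn, only the groups of a contrast in the fit, all 32 human libraries in the fit of a line, each line left out of the average, and list members that no other list holds. Where a group kept 1 library, that library was assumed to vary like the other groups. After seeing the data, 2 CAL27 libraries that stood apart were also left out, and a test of the difference between the 4 lines' effects was added. For the average, genotype or treatment labels were redrawn within each line 24 times, which with the real labels makes 25 splits. Groups of 2 libraries were not split, since too few splits exist.

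The fits were tested on simulated counts with the real library sizes, in the N173S or panKO contrast under PBS, with 100 genes changed 2-fold and 100 changed 1.5-fold. Recovery at low counts was not given apart and may be lower. edgeR recovered 83% and 67% of them in HGC27 (15820 genes), 78% and 38% in OE21 (15655 genes), 56% and 8% in OE33 (14980 genes), 0% and 0% in CAL27 (16950 genes), 86% and 56% in the average (19979 genes) and 93% and 81% in B16F10 (15238 genes). Calls among unchanged genes numbered 8, 8, 3, 2, 11 and 8 in that order. In CAL27, the line with the most counts (22.4 to 24.4 M), simulated changes of either size were therefore not called, and in OE33 few 1.5-fold ones were, so a missing call there does not show that a gene kept its level.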

Results

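The data were gene counts from poly-A-selected RNA of 4 human cancer cell lines and 1 mouse line, in 52 libraries that made 26 groups of 2. HGC27 is a gastric carcinoma line, OE21 an oesophageal squamous carcinoma line, OE33 an oesophageal adenocarcinoma line and CAL27 a tongue squamous carcinoma line. Each human line had WT cells and cells labelled N173S, a change in the Z-nucleic-acid-binding (Zα) domain of ADAR1 p150, and each was treated with PBS or with interferon beta (IFNB). ADAR1 edits adenosines in double-stranded RNA, p150 is its interferon-induced isoform and p110 its constitutive isoform. B16F10, a mouse melanoma line, had 5 genotypes under PBS or interferon beta (IFNb): WT, panKO (knockout of both isoforms per the labels), and panKO with p110, p150 or a Zα-mutant p150 (ZaMUTp150) put back. Total counts per library ran from 12.6 to 17.2 M in HGC27, 13.4 to 17 in OE21, 14.2 to 19.5 in OE33, 22.4 to 24.4 in CAL27 and 15.5 to 18.6 in B16F10. Between 22816 and 26094 genes had a count in the human libraries, and between 19990 and 24133 in the mouse libraries. Changes are log2 fold changes ± SE from edgeR with 2 libraries against 2 (n = 2 per group), and genes that rose or fell passed an adjusted p of 0.05. Where a group held no counts of a gene, the fold is a lower bound at a floor of 3 counts over the group, and with 1 to 3 counts it is a ratio with its 95% counting interval. Both cover counting error only. For each gene list the count of members that passed over all genes is followed in brackets by the count adjusted over the list alone.

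ADAR lies on GRCh38 chromosome 1 from 154581695 to 154628013 on the minus strand (ENSG00000160710). Under PBS its mean level was 169 ± 11.7 CPM (SD, n = 2) in WT HGC27, 170 ± 1.29 in OE21, 233 ± 18.3 in OE33 and 321.5 ± 42.6 in CAL27. The N173S cells under PBS held 180 ± 4.81, 193 ± 10.1, 229.5 ± 28.3 and 239 ± 89.1 in the same order. With IFNB the WT levels were 565 ± 5.21, 355 ± 25.4, 546 ± 13.2 and 842 ± 409, and the N173S levels 520 ± 56.3, 347 ± 49.4, 692 ± 166 and 874 ± 62. IFNB raised ADAR by 1.74 ± 0.0764 in WT HGC27, 1.06 ± 0.108 in OE21 and 1.23 ± 0.173 in OE33, and by 1.53 ± 0.0762, 0.84 ± 0.107 and 1.59 ± 0.175 in their N173S cells. In CAL27 the changes were 1.39 ± 0.397 (adjusted p = 0.254) and 1.87 ± 0.403 (adjusted p = 0.1). The OE33 WT rise ended at adjusted p = 0.117 to 0.25 without any of the 4 libraries it compared, and the OE21 N173S rise at 0.0769 without N173S PBS replicate 2. No difference in ADAR between N173S and WT cells was called in any line or treatment (adjusted p from 0.193 to 0.973), with estimates from -0.43 ± 0.391 in CAL27 under PBS to 0.34 ± 0.17 in OE33 with IFNB, which does not show equal levels. Gene counts cannot show a single-residue edit.

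In B16F10 the Adar level under PBS was 58.8 ± 2.14 CPM (SD, n = 2) in WT, 97.8 ± 1.76 in libraries labelled panKO, 47.5 ± 1.86 with p110, 35.4 ± 3.9 with p150 and 46.8 ± 1.05 with ZaMUTp150. With IFNb the levels were 126 ± 10.8, 150 ± 4.9, 146 ± 4.63, 65.8 ± 0.0803 and 77.3 ± 1.13. Adar was 0.73 ± 0.0605 higher in panKO than in WT under PBS and 0.25 ± 0.0539 higher with IFNb. The panKO libraries were therefore not lower in the targeted gene, and gene-level counts do not check the knockout, the restored isoforms or the Zα mutation. Genotypes below are those of the labels, and every direction drawn between them rests on the labels alone. The labels used here do not separate a genotype from the derived line that carries it. Differences between derived lines that do not come from ADAR1 therefore cannot be told apart from the genotype.

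The treatment itself was the first comparison: which genes interferon beta moved in each line. In HGC27 the antiviral genes went up, some of them from near absence. Of 42 interferon-stimulated genes tested, 41 rose in WT cells (41 adjusted over the list alone) with a median of 4.33, and 40 of 42 rose in N173S cells (40 over the list alone) with a median of 3.91. OAS1, which makes the second messenger of RNase L, rose by 10.16 ± 0.167. OAS2 rose by 10.60 ± 0.164. OASL, their catalytically inactive relative, was at least 821-fold higher, and MX2, an antiviral GTPase, 10400-fold (counting interval 1870 to 412000) higher. Nucleic acid sensors rose in 7 of 9 genes (7 over the list alone), among them DHX58, a regulator of the RIG-I family, by 5.66 ± 0.224. MHC class I genes rose in 17 of 21 (18 over the list alone), such as the immunoproteasome subunit PSMB9 (2.43 ± 0.125) and the peptide transporter TAP1 (2.16 ± 0.0865). LGALS9, a galectin ligand of immune receptors, rose by 5.84 ± 0.283, and APOL6, of the apolipoprotein L family, by 4.10 ± 0.25. The largest falls were in MIR600HG (-1.84 ± 0.232), the ceramide kinase CERK (-1.21 ± 0.0757), FAM172A (-1.02 ± 0.14) and MTURN (-0.90 ± 0.106). edgeR called 278 genes up and 102 down in WT cells and 247 and 69 in N173S cells, of 16159. With 1 library left out, the WT calls numbered 211 without WT IFNB replicate 2 and 198 without WT PBS replicate 1, and the N173S calls 188 without N173S PBS replicate 1 and 208 without N173S PBS replicate 2.

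In OE21 the antiviral genes also rose. Interferon-stimulated genes rose in 43 of 46 in WT cells (46 adjusted over the list alone; median 2.45) and 43 of 46 in N173S cells (45; median 2.10). MX2 rose by 7.28 ± 0.206, TRIM22, an antiviral ubiquitin ligase, by 5.19 ± 0.223, LAMP3, a lysosomal membrane protein, by 4.54 ± 0.166, and CMPK2, a mitochondrial nucleotide kinase, by 4.30 ± 0.254. Sensors rose in 6 of 12 genes (6 over the list alone), with IFIH1 (MDA5), a sensor of long double-stranded RNA, up by 2.42 ± 0.135. Cell death genes rose in 3 of 27 (4 over the list alone), and those with the largest rises, APOL1 (2.14 ± 0.23) and APOL6 (1.89 ± 0.139), are interferon-induced apolipoprotein L genes. The 3 genes that fell were the iron regulator ACO1 (-1.05 ± 0.137), RFLNB (-0.77 ± 0.147) and CERK (-0.68 ± 0.097). ACO1 lost its call without WT IFNB replicate 1 or WT IFNB replicate 2 (adjusted p = 0.0507 to 0.0683), while RFLNB (0.187 to 0.659) and CERK (0.081 to 0.152) lost theirs without any of the 4 libraries. The calls numbered 131 up and 3 down in WT cells and 210 and 14 in N173S cells. WT cells gave 88 without WT PBS replicate 1. N173S cells gave 5609 without N173S IFNB replicate 1, 464 without N173S IFNB replicate 2, 102 without N173S PBS replicate 1 and 89 without N173S PBS replicate 2.

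OE33 cells answered IFNB with a rise in all 46 interferon-stimulated genes tested in WT cells (46 adjusted over the list alone; median 3.13) and in 46 of 46 in N173S cells (46; median 4.29). OAS2 rose by 8.0 ± 0.257, the membrane antiviral protein IFITM1 by 6.73 ± 0.197, IFI44L by 6.69 ± 0.166 and BST2 (tetherin), which holds budding virions at the cell surface, by 6.60 ± 0.342. ZBP1, the other Zα-domain sensor of Z-form nucleic acid and a trigger of necroptosis, rose by 4.98 ± 0.295 in WT and 6.35 ± 0.3 in N173S cells. The checkpoint ligands and MHC class II list held LGALS9 (3.71 ± 0.217), with 3 of 13 members up (6 over the list alone). ACO1 changed by -1.15 ± 0.133 and LINC01963 by -1.11 ± 0.153, and both lost their calls without any of the 4 libraries (adjusted p = 0.0553 to 0.104 and 0.0982 to 0.234). Calls came to 142 up and 2 down in WT cells and 225 and 27 in N173S cells, of 15327. With 1 library left out, the WT count fell each time. The N173S count rose without either N173S IFNB library and fell without either N173S PBS library. Replicate variation was 49.7 times that of counting in N173S IFNB and 2.46 to 8.76 times in the other OE33 groups.

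In CAL27 the antiviral genes rose, and some cytokines with them: of 24 interferons, cytokines and chemokines 5 rose in WT cells (14 adjusted over the list alone, with 1 down; median 0.96; camera adjusted p = 9.25e-16, and 0.0148 with an estimated correlation) and 9 in N173S cells (16 and 1; median 1.43; adjusted p = 6.27e-10 and 0.0427). The lymphocyte attractants CXCL10 and CXCL11 rose by 8.27 ± 0.501 and 7.60 ± 0.413 in WT cells, ZBP1 by 9.47 ± 0.526 and the transcription factor BATF2 by 7.75 ± 0.438. Interferon-stimulated genes rose in 42 of 46 in WT cells (46 adjusted over the list alone; median 3.77) and 39 of 46 in N173S cells (45; median 3.26). IDO1, a tryptophan-degrading enzyme, rose by 6.52 ± 0.359 and DHX58 by 3.91 ± 0.263. Falls were called for LINC01963 (-2.13 ± 0.326), NANOS1 (-2.10 ± 0.261), LOXL4, a collagen cross-linking oxidase (-1.96 ± 0.231), and DANCR (-1.80 ± 0.31). The LINC01963 call was lost without WT IFNB replicate 2, WT PBS replicate 1 or WT PBS replicate 2 (adjusted p = 0.0649 to 0.275) and that of DANCR without WT IFNB replicate 1, WT PBS replicate 1 or WT PBS replicate 2 (0.0646 to 0.376). Those of NANOS1 and LOXL4 were lost without WT PBS replicate 1 or WT PBS replicate 2 (adjusted p = 0.117 to 0.141 and 0.117 to 0.144). Calls came to 216 up and 14 down in WT cells and 206 and 16 in N173S cells. Replicates lay far apart in WT IFNB and N173S PBS, whose replicate variation was 178 and 134 times that of counting, and 1 library of each stood apart. WT calls numbered 34 without WT PBS replicate 1 and 33 without WT PBS replicate 2, and N173S calls 42 without N173S IFNB replicate 1, 50 without N173S IFNB replicate 2, 79 without N173S PBS replicate 1 and 100 without N173S PBS replicate 2.

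**Figure D1:**
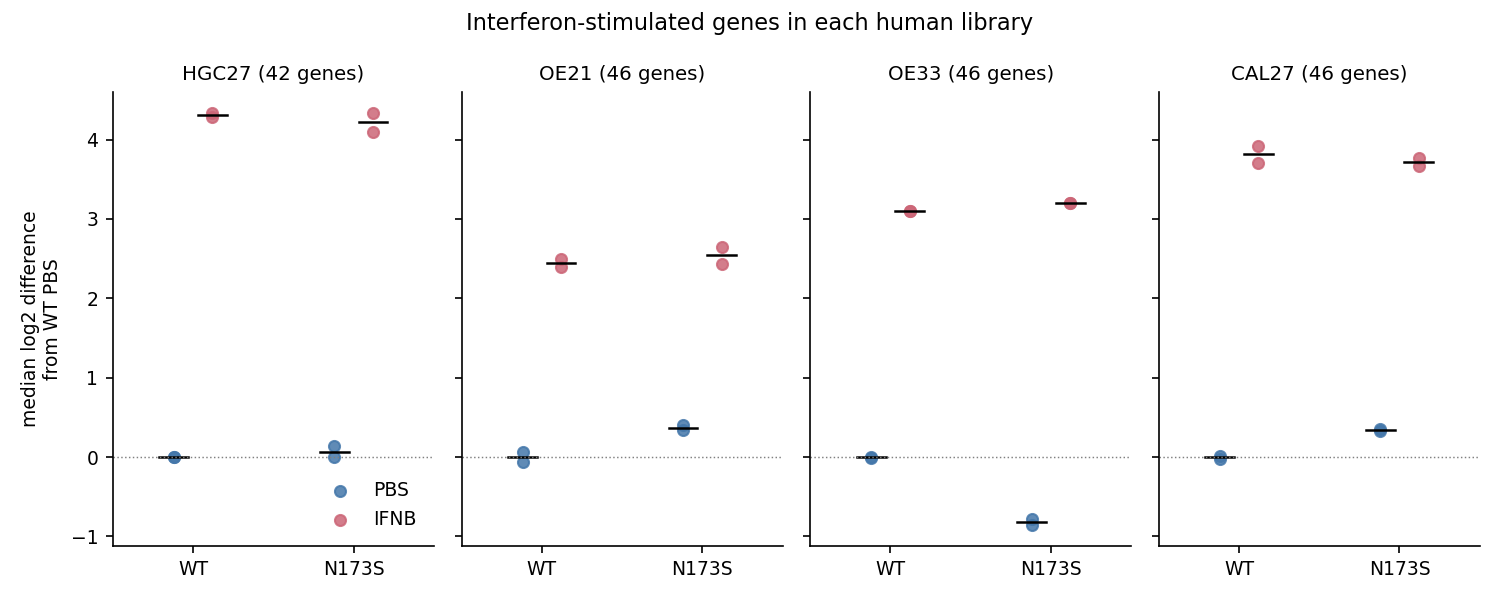
Median log2 difference of the interferon-stimulated genes from the WT PBS mean in each human library, by line, genotype and treatment, with 1 point per library. IFNB libraries lay from 2.39 (OE21) to 4.34 (HGC27), and the OE33 N173S PBS libraries at -0.78 and -0.86.

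Averaged over the 4 lines, the response was that of the interferon programme, with OAS2 up by 6.88 ± 0.127, TRIM22 by 5.88 ± 0.203, OAS1 by 5.47 ± 0.0878 and the mitochondrial protein IFI6 by 5.41 ± 0.175. Interferon-stimulated genes rose in 46 of 46 in WT cells (46 adjusted over the list alone; median 3.57) and 44 of 46 in N173S cells (45; median 3.40). The mitotic kinases AURKA and PLK1 changed by -0.43 ± 0.047 and -0.43 ± 0.0589. In the cell cycle list 4 of 32 genes fell (9 over the list alone; median -0.11; camera adjusted p = 7.41e-05, and adjusted p = 0.00196 with an estimated correlation). Among the genes down in every line were NANOS1 (-1.24 ± 0.158), LINC01963 (-1.13 ± 0.105), CERK (-1.03 ± 0.0526) and DANCR (-0.96 ± 0.103). The average gave 501 rises and 263 falls in WT cells and 519 and 305 in N173S cells, of 20473. The WT count was 1215 without CAL27 WT IFNB replicate 1 and the N173S count 1438 without CAL27 N173S PBS replicate 2.

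The next comparison asked what the Zα-domain change does to expression in each line, and each line had 1 edited line, so the edit and the line derived cannot be separated. In HGC27 the N173S cells held less of the mesenchymal programme. The matrix protein fibronectin (FN1) changed by -4.05 ± 0.22 and the actin-binding TAGLN by -3.37 ± 0.123 under PBS, and by -3.93 ± 0.213 and -3.22 ± 0.116 with IFNB. Of 20 mesenchymal genes 15 fell under PBS (17 adjusted over the list alone; median -0.98; camera adjusted p = 9.31e-13) and 14 with IFNB (15; median -1.02; adjusted p = 3.47e-10). Fibroblast and endothelial markers fell in 6 of 8 in HGC27 N173S cells under PBS (6 adjusted over the list alone; adjusted p = 0.0144, and 0.246 with an estimated correlation), with PDGFRB at -2.26 ± 0.399. The collagen gene COL5A3 changed by -4.48 ± 0.288, VASH1, an inhibitor of vessel growth, by -4.27 ± 0.308 and the epithelial membrane protein EMP1 by -4.16 ± 0.174. Keratin KRT4 was 177-fold (counting interval 60.2 to 860) lower under PBS and changed by -4.92 ± 0.252 with IFNB. Higher under PBS were DMKN, an epidermal secreted protein (2.66 ± 0.135), CCSER1 (2.24 ± 0.307) and C14orf180 (2.10 ± 0.179), and with IFNB SPON2 (2.26 ± 0.284) and OLFM3 (2.18 ± 0.242). CRYM fell by 4.35 ± 0.305 with IFNB. TRIM51CP, a pseudogene whose reads may be shared with its relatives, rose by 2.77 ± 0.134 and 3.01 ± 0.135.

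Among stress and immune genes of HGC27 N173S cells some were lower and some higher. The stress effector NUPR1 changed by -0.99 ± 0.118 and CHAC1, a glutathione-degrading enzyme, by -1.31 ± 0.245. Of the 26 integrated stress response genes 12 fell under PBS (12 over the list alone; adjusted p = 0.000396, and adjusted p = 0.136 with an estimated correlation). STING1, the adaptor of DNA sensing, changed by -0.85 ± 0.124 and -0.90 ± 0.112 under PBS and IFNB, and BST2 by -1.70 ± 0.148. MHC class I genes fell in 10 of 21 with IFNB (11 over the list alone; adjusted p = 0.00752, and 0.238 with an estimated correlation), among them HLA-E (-0.58 ± 0.0648) and PSMB10 (-0.88 ± 0.17), while PSMB8 rose by 0.67 ± 0.092 under PBS. The mitotic activators CDC20 and CCNB1 rose by 0.84 ± 0.066 and 0.42 ± 0.0654 under PBS. Interferon-stimulated genes as a list had a median of 0.045 under PBS (adjusted p = 0.163; 10 up, 4 down, 13 and 4 over the list alone) and -0.15 with IFNB (adjusted p = 0.183; 7 up, 12 down, 7 and 14 over the list alone). edgeR called 1685 genes up and 1785 down under PBS and 1906 and 2063 with IFNB, of 16159. The PBS count was 1707 without N173S PBS replicate 1, 2075 without N173S PBS replicate 2 and 1938 without WT PBS replicate 2, and the IFNB count 2367 without WT IFNB replicate 2. The response to IFNB differed between genotypes in BST2 (1.40 ± 0.166) and DDIT4, a stress-induced inhibitor of mTORC1 (1.26 ± 0.107), out of 541 genes at an unadjusted p under 0.05. Without N173S PBS replicate 1 BST2 had an adjusted p of 0.0515 and the count was 1.

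In OE21 N173S cells under PBS, genes of squamous differentiation were lower and several inflammatory genes higher. The surface protease TMPRSS11D changed by -7.62 ± 0.309, the epithelial chemokine CXCL14 by -7.55 ± 0.391, PODXL2 by -7.26 ± 0.304 and the tight junction gene CLDN7 by -4.41 ± 0.163 under PBS. In that condition 16 of 29 epithelial and squamous genes fell while 3 rose (17 and 3 adjusted over the list alone; adjusted p = 0.00179, and 0.335 with an estimated correlation). Among those that rose were keratin KRT14 (1.41 ± 0.152) and the lineage factor TP63 (1.02 ± 0.0982). With IFNB 12 fell and 3 rose (13 and 5 over the list alone) and the list did not pass (adjusted p = 0.0746, or 0.0397 without OE21 N173S IFNB replicate 2). Of 17 mesenchymal genes 4 rose and 3 fell in each condition (4 and 3 over the list alone; adjusted p = 0.562 under PBS and 0.857 with IFNB): under PBS vimentin (VIM) rose by 2.64 ± 0.116 and the actin-binding TAGLN changed by -1.80 ± 0.301. Under PBS and IFNB the collagenase MMP13 rose by 3.81 ± 0.125 and 3.06 ± 0.113, and the methionine sulfoxide reductase MSRB3 by 3.40 ± 0.317 and 3.13 ± 0.317. Under PBS, the neutrophil chemokine CXCL8 rose by 3.14 ± 0.167 and the pattern receptor PTX3 by 3.27 ± 0.311. Cytokines as a list had 7 up and 3 down of 18 (7 and 3 over the list alone; adjusted p = 0.0394, and 0.33 with an estimated correlation), and with IFNB 10 and 3 (10 and 3; adjusted p = 0.00236, and 0.111 with an estimated correlation). With IFNB, the cytokine IL32 rose by 3.27 ± 0.337 and the histone gene H2BC11 by 3.02 ± 0.282, and PODXL2, TMPRSS11D and CXCL14 changed by -7.19 ± 0.292, -6.65 ± 0.277 and -6.36 ± 0.358.

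Interferon-stimulated genes of OE21 N173S cells were higher under PBS in 20 of 46 and lower in 3 (20 and 3 over the list alone; median 0.40; camera adjusted p = 0.00179, and adjusted p = 0.343 with an estimated correlation). The helicase DDX60 rose by 2.74 ± 0.294 and RTP4, an interferon-induced receptor transporter, by 2.73 ± 0.489, whereas LY6E fell by 0.85 ± 0.144. With IFNB 7 rose and 8 fell (8 and 8 over the list alone; median -0.025, mean 0.04; adjusted p = 0.929 for a fall), and RSAD2 (viperin) fell by 1.06 ± 0.159. AIM2, a sensor of cytosolic DNA, changed by -4.83 ± 0.284 and -4.12 ± 0.203, HLA-B by -1.17 ± 0.15 and -1.05 ± 0.145, and the stress genes NUPR1 and GDF15 by -4.73 ± 0.387 and -3.37 ± 0.464 under PBS. GPNMB, a melanosomal glycoprotein also expressed in epithelia, fell by 5.27 ± 0.11. Calls came to 3307 up and 3478 down under PBS and 2034 and 2282 with IFNB. With 1 library left out, PBS calls numbered 3765 without N173S PBS replicate 1, 3765 without N173S PBS replicate 2, 4290 without WT PBS replicate 1 and 3732 without WT PBS replicate 2. IFNB calls rose without N173S IFNB replicate 2 and fell without either WT IFNB library. The genotype changed the IFNB response of IFIT1 (difference -1.55 ± 0.171) and IFIT3 (-1.28 ± 0.137), RNA-binding antiviral proteins, of 1236 genes at an unadjusted p under 0.05. Both lost their calls without any of 6 of the 8 libraries (adjusted p = 0.0834 to 0.315 and 0.183 to 0.315). The response count rose without either N173S IFNB library, whose replicates lay apart, and fell without any other.

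In OE33 the N173S cells held less of the interferon programme before treatment. Under PBS 21 of 46 interferon-stimulated genes fell (31 adjusted over the list alone; median -0.76, or -0.71 with genes at 0 counts at their bound; camera adjusted p = 3.33e-21), among them SAMD9L (-3.52 ± 0.27), an antiproliferative antiviral factor, and RTP4 (-2.85 ± 0.248). MHC class I genes fell in 12 of 21 (16; adjusted p = 5.94e-11), with HLA-F at -1.49 ± 0.202, and NF-κB targets in 8 of 22 (13; adjusted p = 1.25e-07). Immune cell markers in OE33 N173S cells had 3 of 5 down under PBS (4; adjusted p = 2.66e-05, and 0.0701 with an estimated correlation), with CD79A, a B cell receptor chain, at -2.54 ± 0.314. The chemokines CXCL1 and CXCL3 stood at -3.87 ± 0.157 and -3.42 ± 0.227. The steroid- and aldehyde-reducing enzymes AKR1C3, AKR1C1 and AKR1C2 rose by 5.63 ± 0.247, 5.37 ± 0.197 and 4.31 ± 0.184, near-identical genes whose reads the counting could share, and the progestin receptor PAQR5 by 4.11 ± 0.31. SOX2, a foregut and squamous lineage factor, rose by 4.39 ± 0.467. Lower were the activin antagonist FST (-5.23 ± 0.212), the collagenase MMP1 (-4.96 ± 0.193) and CLTRN (-4.24 ± 0.424), and the urothelial tetraspanin UPK1B was 224-fold (counting interval 76.5 to 1090) lower.

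With IFNB the interferon genes of OE33 N173S cells did not lie below WT as a list: 5 of 46 were higher than in WT and 1 lower (12 and 1 adjusted over the list alone; median 0.25; camera adjusted p = 0.00656, and adjusted p = 0.104 with an estimated correlation). The response itself, a test that shares the PBS libraries with the comparison under PBS, was larger in N173S cells in 8 of 46 genes (37 over the list alone; median 1.06; adjusted p = 6.05e-71). Differences were 3.37 ± 0.337 for SAMD9L, 2.56 ± 0.298 for RTP4, 2.55 ± 0.19 for IFIT1, 2.16 ± 0.257 for MX2 and 1.43 ± 0.169 for the DNA sensor IFI16. Each of these lost its call without any of 6 of the 8 libraries, with adjusted p = 0.139 to 0.342, 0.27 to 0.445, 0.0914 to 0.171, 0.269 to 0.491 and 0.342 to 0.553 in that order. AKR1C3 and AKR1C1 were still higher with IFNB (5.14 ± 0.25 and 4.96 ± 0.2), as were the cytoskeletal gene MAP1B (4.76 ± 0.391) and PAQR5 (4.56 ± 0.312). FST (-4.85 ± 0.2), the adhesion gene CEACAM6 (-4.24 ± 0.142), MMP1 (-4.18 ± 0.174) and the annexin ANXA10 (-4.13 ± 0.161) were lower. The stress gene DDIT4 fell by 1.63 ± 0.168, in a list with 8 of 24 down (10; adjusted p = 5.12e-05, and 0.104 with an estimated correlation). Calls came to 429 up and 556 down under PBS, 473 and 643 with IFNB, and 10 and 0 for the response. With 1 library left out, PBS calls numbered 301 without WT PBS replicate 1, 270 without WT PBS replicate 2, 343 without N173S PBS replicate 1 and 297 without N173S PBS replicate 2. IFNB and response calls rose without either N173S IFNB library, whose replicates lay apart, and fell without any other library compared.

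In CAL27 few genes passed between N173S and WT cells, and the chemokine genes leaned upwards. Under PBS the 6 calls were all falls: OLFM4, a secreted stem cell marker (-4.41 ± 0.363), the endogenous retroviral envelope gene ERVMER34-1 (-3.77 ± 0.29), keratin KRT1 (-3.01 ± 0.234) and LOXL4 (-2.76 ± 0.241). GPC4, a cell surface proteoglycan (-5.27 ± 0.36), and TMX4, a thioredoxin-related membrane protein (-2.24 ± 0.22), were the other 2 and are named after their values were seen. With IFNB the chemokine CCL20 rose by 3.41 ± 0.306, and OLFM4 (-4.12 ± 0.361), GPC4 (-4.03 ± 0.308), ERVMER34-1 (-3.66 ± 0.294), KRT1 (-3.05 ± 0.236) and TMX4 (-2.49 ± 0.23) fell. Under PBS none of 24 cytokine and chemokine genes was called, 15 rose when adjusted over the list alone, the median was 1.31 (1.09 with genes at 0 counts at their bound), and camera gave an adjusted p of 9.78e-16. NF-κB targets followed with 13 up over the list alone and none over all genes (median 0.88; adjusted p = 3.44e-13), and interferon-stimulated genes with 3 (median 0.49; adjusted p = 1.03e-06). With IFNB the cytokine median was 1.15 (1 up, 13 over the list alone; adjusted p = 1.25e-14) and the interferon-stimulated median -0.12 (0 up, 0 over the list alone; adjusted p = 0.666). edgeR called 0 up and 6 down under PBS, 1 and 5 with IFNB, and none for the response. At an unadjusted p under 0.05 there were 1225, 1222 and 419 genes, and DESeq2 called 193, 239 and 0. These calls depended on the replicates: OLFM4, ERVMER34-1, KRT1 and LOXL4 had an adjusted p of 0.141 to 0.227, 0.105 to 0.227, 0.119 to 0.227 and 0.141 to 0.416 without any of the 4 PBS libraries. CCL20 had 0.06 to 0.468 without any of the 4 IFNB libraries, and OLFM4, GPC4, ERVMER34-1 and KRT1 had 0.45 to 0.525, 0.426 to 0.468, 0.426 to 0.468 and 0.426 to 0.468 without N173S IFNB replicate 1 or N173S IFNB replicate 2. The PBS count was 0 without any of the 4 libraries, and the IFNB count 0 without N173S IFNB replicate 1 and 0 without N173S IFNB replicate 2. Without the 2 libraries that stood apart, an alternative added after seeing the data, the counts were 964 under PBS, 1581 with IFNB, 22 for the response and, for IFNB itself, 5538 in WT and 3937 in N173S cells.

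Averaged over the 4 lines, N173S cells held less of a few surface and signalling genes, by amounts that differed between lines. The proteoglycan GPC4 changed by -2.81 ± 0.108 under PBS and -2.42 ± 0.0987 with IFNB, the integrin ligand NPNT by -2.48 ± 0.18 and -2.14 ± 0.173. With IFNB the Hedgehog signal transducer SMO changed by -1.77 ± 0.131 and TMEM98 by -1.39 ± 0.186. The SMO average rests on OE21 (-5.88, against -0.30 in HGC27, -0.44 in OE33 and -0.47 in CAL27), and under PBS NPNT stood at -6.42 in OE33 and -0.47 in HGC27. Rises were smaller: metallothionein MT2A by 0.93 ± 0.21, the growth factor PDGFB by 0.60 ± 0.0954 and RPP40 by 0.45 ± 0.0755 under PBS. With IFNB MAPRE2, a microtubule end-binding protein, rose by 0.63 ± 0.115 and DUBR by 0.55 ± 0.102. The antisense transcripts DPH5-DT (0.59 ± 0.0787) and KDM4A-AS1 (0.61 ± 0.136) cannot be told from their neighbours without strand. Presenilin 2 (PSEN2) rose by 0.63 ± 0.145 and 0.70 ± 0.14 under PBS and IFNB, and SUCLA2 (0.55 ± 0.151) and TRIM36 (0.54 ± 0.155) rose with IFNB. Under PBS, PSEN2 lost its call without HGC27 N173S PBS replicate 1 (adjusted p = 0.0558). With IFNB SUCLA2 lost its call without any of 9 libraries (0.0508 to 0.105) and TRIM36 without any of 12 (0.0598 to 0.0909).

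MHC class I genes fell on average in 5 of 22 under PBS (6 adjusted over the list alone; median -0.22; camera adjusted p = 0.000141, and adjusted p = 0.0709 with an estimated correlation) and in 9 with IFNB (12; median -0.26; adjusted p = 5.84e-05, and 0.0559 with an estimated correlation). HLA-F stood at -0.84 ± 0.166 and -0.89 ± 0.148 and HLA-B at -0.70 ± 0.159 and -0.73 ± 0.158, though under PBS CAL27 stood at 0.41 for HLA-F and 0.22 for HLA-B. TNFSF10 (TRAIL), a death receptor ligand, changed by -1.23 ± 0.143 under PBS. Interferon-stimulated genes had a median of -0.056 under PBS (1 up, 4 down, 1 and 4 over the list alone; adjusted p = 0.959) and -0.014 with IFNB (1 up, 4 down, 1 and 4; mean -0.038; adjusted p = 0.757 for a rise). Under PBS the lines differed, with list medians of 0.045 in HGC27, 0.40 in OE21, 0.49 in CAL27 and -0.76 in OE33, and without OE33 the list turned up (adjusted p = 5.47e-08). Calls came to 346 up and 795 down under PBS and 583 and 1162 with IFNB, of 20473; the IFNB response differed between genotypes in none, with 557 genes at an unadjusted p under 0.05 and 0 called by DESeq2. With 1 library left out, the IFNB count was 1151 without HGC27 N173S IFNB replicate 1, 1142 without HGC27 WT IFNB replicate 2, 1092 without OE21 N173S IFNB replicate 1, 1068 without OE33 N173S IFNB replicate 2, 1114 without CAL27 N173S IFNB replicate 2 and 4870 without CAL27 WT IFNB replicate 1, and the response count 1 without CAL27 WT IFNB replicate 2. Within lines, the response difference of interferon-stimulated genes had a median of -0.20 in HGC27 (camera adjusted p = 2.21e-05, and 0.196 with an estimated correlation), -0.37 in OE21 (9.49e-11 and 0.193) and -0.54 in CAL27 (9.3e-06 and 0.0687), with 6, 9 and 0 genes lower when adjusted over the list alone. In OE33 the median was 1.06 (6.05e-71 and 0.000346), with 37 genes higher over the list alone. limma on the 4 per-line changes, which treats lines as the replicates, called 0 genes under PBS (276 at an unadjusted p under 0.05), 0 with IFNB (1374), 32 for IFNB in WT cells, 3 in N173S cells (IFI35, LAMP3 and STAT2) and 0 for the response difference (172).

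N173S changes had low median correlations between lines, and calls overlapped in the same and in opposite directions. Across 12507 genes, tested in each line and not independent replicates, the median between pairs was -0.0406 under PBS and 0.0846 with IFNB. Above a log2 CPM of 3 it was -0.0515 and 0.158. Pairs with CAL27 gave -0.24 to -0.0555 under PBS and 0.0411 to 0.189 with IFNB, the others -0.0258 to 0.14 and -0.000563 to 0.122. The CAL27 libraries that stood apart lie on opposite sides of the contrast, N173S under PBS and WT with IFNB. GPC4 was the gene down in all 4 lines in both conditions. Down in at least 3 lines were 26 genes under PBS, where independent lines would give 7.13, and 27 with IFNB, against 6.02; up in at least 3 were 9, against 8.18, and 6, against 5.71. In at least 2 lines 636 genes were up and 600 down under PBS, against 417 and 381. With IFNB these were 408 and 484, against 280 and 300. HGC27 and OE21 shared 549 rises and 502 falls under PBS, against 326 and 299. With IFNB these were 302 and 372, against 201 and 222. Opposite calls were fewer than expected (423 against 625 under PBS and 369 against 423). Between HGC27 and OE33 opposite calls (120 against 69.1 under PBS and 130 against 90.2 with IFNB) and shared falls (59 against 33.3 and 78 against 45) exceeded their expectation, and shared rises did not (25 against 35.8 and 40 against 45.1). Between OE21 and OE33 opposite calls (159 against 134 and 139 against 89.4), shared falls (90 against 62.1 and 87 against 44.3) and shared rises (80 against 71.9 and 78 against 45) all did. A test of the differences between lines called 3734 genes under PBS and 2719 with IFNB, of 20473, and 206 for the IFNB response of WT cells and 554 for that of N173S cells. It pooled the spread of all 32 libraries, those 2 CAL27 ones included, which may add to these counts. Neither it nor the correlations were run without them.

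In B16F10, IFNb was first compared with PBS within each genotype. In WT cells 43 of 46 interferon-stimulated genes rose (43 adjusted over the list alone; median 2.69, or 2.57 with genes at 0 counts at their bound), with Ifi44 up by 6.60 ± 0.205 and Oas2 by 6.18 ± 0.153. Apol9a and Apol9b, near-identical lipid-binding genes whose reads could be shared, rose by 6.98 ± 0.232 and 6.22 ± 0.197, and Zbp1 was at least 33.3-fold higher. MHC class I genes rose in 15 of 20 (16), with the immunoproteasome subunit Psmb8 at least 12.7-fold higher, and cell cycle genes fell in 16 of 32 (16; median -0.14; adjusted p = 7.41e-09). Adam12, a metalloprotease, changed by -1.13 ± 0.203, the mitochondrial transcript mt-Nd1 by -0.94 ± 0.0642 and the NF-κB inhibitor Nfkbia by -0.84 ± 0.135. Fbxo41 changed by -0.74 ± 0.221 but lost its call without WT IFNb replicate 1, WT IFNb replicate 2 or WT PBS replicate 2 (adjusted p = 0.0712 to 0.272). In libraries labelled panKO 43 rose and 1 fell (43 and 1 over the list alone; median 0.71), with p110 44 rose and 2 fell (44 and 2; median 2.04), with p150 43 rose (44; median 2.67), and with ZaMUTp150 43 rose (44; median 2.18, or 2.16 at the bound). Calls were 627 up and 454 down in WT, 3162 and 3013 in panKO, 5095 and 4945 with p110, 1268 and 1022 with p150, and 1207 and 1076 with ZaMUTp150, of 16134. WT calls numbered 647 without WT PBS replicate 1 and 613 without WT PBS replicate 2. Those with p150 numbered 1421 without panKO_p150 IFNb replicate 1, 1404 without panKO_p150 IFNb replicate 2 and 1203 without panKO_p150 PBS replicate 1, and those with ZaMUTp150 1441 without panKO_ZaMUTp150 IFNb replicate 1, 1397 without panKO_ZaMUTp150 IFNb replicate 2 and 1295 without panKO_ZaMUTp150 PBS replicate 1.

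**Figure D2:**
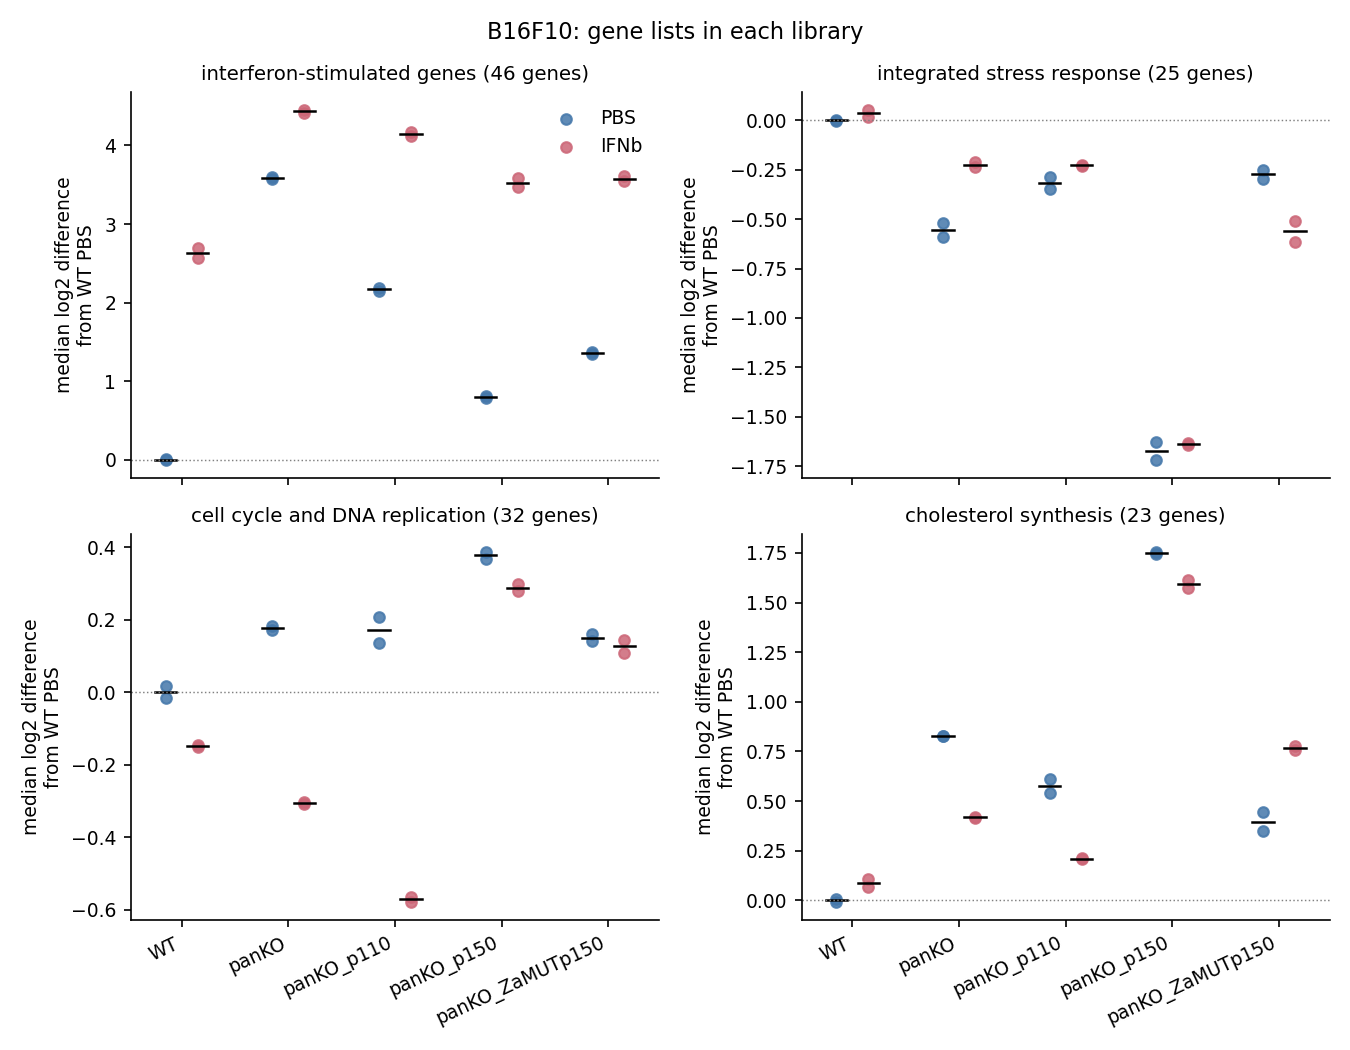
Median log2 difference of each gene list from the WT PBS mean in every B16F10 library, by genotype, with 1 point per library and PBS and IFNb apart. Under PBS the interferon-stimulated genes stood at 0.80 and 0.79 with p150, 1.35 and 1.36 with ZaMUTp150 and 2.19 and 2.14 with p110; the cholesterol list was chosen after the results were seen.

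Libraries labelled panKO were compared with WT, where loss of ADAR1 and the derived line cannot be separated. Without interferon they already held the antiviral programme: 43 of 46 interferon-stimulated genes were higher under PBS (43 adjusted over the list alone; median 3.71, or 3.64 with genes at 0 counts at their bound; camera adjusted p = 6.76e-31). Oas2 rose by 7.50 ± 0.13, Apol9a by 8.67 ± 0.18, Apol9b by 7.43 ± 0.166 and the nuclear sensor Mndal by 7.03 ± 0.245. With IFNb 44 were higher (44; median 1.64). Zbp1 was at least 48.3-fold higher under PBS and rose by 3.12 ± 0.166 with IFNb, and the death ligand Tnfsf10 was 91.6-fold (counting interval 16.1 to 3660) higher. Nlrc5 rose by 6.61 ± 0.203, in an MHC class I list with 17 of 20 up (17; adjusted p = 4.61e-08). With IFNb the interferon-inducible GTPase Iigp1 rose by 6.03 ± 0.193, Inka2 by 5.24 ± 0.148, the integrin Itgb8 by 5.18 ± 0.194 and Slfn8 by 4.75 ± 0.17. The replication-linked protease Fam111a changed by -7.08 ± 0.327 and -7.52 ± 0.334, the junctophilin Jph2 by -6.66 ± 0.258 and -7.37 ± 0.272. Galnt6 changed by -5.96 ± 0.281 and the costimulatory receptor Tnfrsf9 by -5.30 ± 0.331 under PBS, and with IFNb Gstp2 by -5.47 ± 0.278 and the interleukin receptor inhibitor Sigirr by -5.40 ± 0.323. Integrated stress response genes fell in 18 of 25 under PBS (19; adjusted p = 4.43e-06), such as the folate enzyme Aldh1l2 (-1.86 ± 0.049), though Atf3 rose by 1.00 ± 0.0578. The 6 libraries of panKO in both treatments and of p110 with IFNb, singled out after seeing the data, also detected more genes, from 22670 to 24133, than the other 14, from 19990 to 21208. edgeR called 5046 genes up and 4709 down under PBS and 5548 and 5255 with IFNb.

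**Figure D3:**
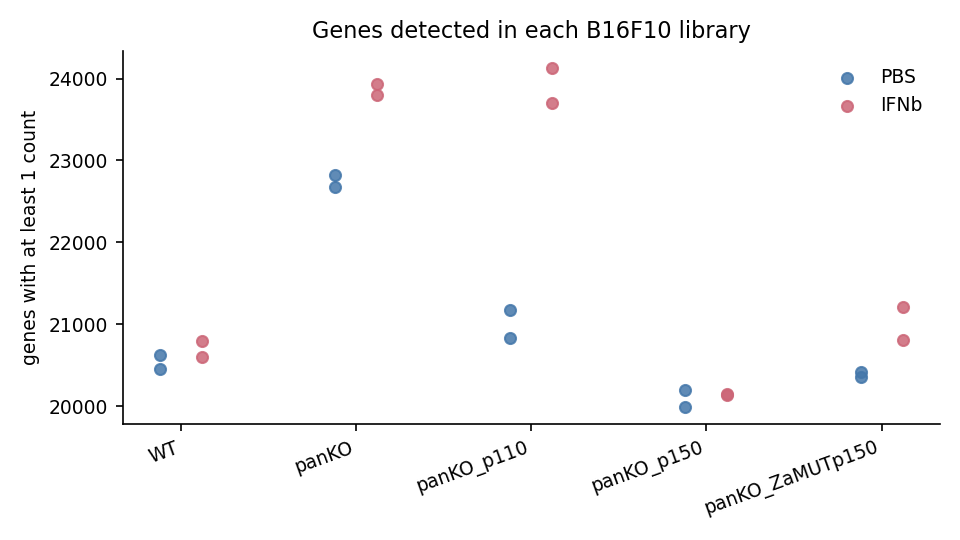
Number of genes with at least 1 count in each B16F10 library, by genotype and treatment, with 1 point per library. The panKO libraries, and the p110 libraries with IFNb, lay above every other library.

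Putting p150 back, per the labels, was compared with panKO. The interferon genes were lower: 44 of 46 fell under PBS (44 adjusted over the list alone; median -2.68; adjusted p = 2.69e-35) and 43 with IFNb (43; median -0.94; adjusted p = 4.28e-13). Apol9b, Apol9a, Mndal and Ifi44 changed by -7.46 ± 0.17, -7.30 ± 0.157, -6.08 ± 0.222 and -5.80 ± 0.185 under PBS. With IFNb the scavenger receptor Stab2, the DNA sensor Ifi204, Itgb8 and Neurl3 changed by -6.23 ± 0.336, -5.26 ± 0.324, -5.04 ± 0.193 and -4.79 ± 0.319. Stress genes fell in 22 of 25 under PBS (22; adjusted p = 7.58e-12) and 23 with IFNb (23; adjusted p = 4.28e-13), with Atf3 at -3.85 ± 0.0808 and -4.21 ± 0.0712. Melanocyte genes rose in 15 of 16 under PBS (15; median 0.44; adjusted p = 1.89e-08), with the melanosomal transporter Oca2 up by 1.61 ± 0.0589. Stc1, Adam12, Smtnl2 and Rapgef5 rose by 3.20 ± 0.188, 3.01 ± 0.16, 2.98 ± 0.204 and 2.97 ± 0.277 under PBS. With IFNb, Smtnl2, Kbtbd11, Cck and Adam12 rose by 3.98 ± 0.234, 3.89 ± 0.0991, 3.79 ± 0.155 and 3.55 ± 0.164. The panKO libraries, which stand apart in both treatments, detected 22670 to 23930 genes and those with p150 19990 to 20198. Calls came to 3986 up and 4221 down under PBS and 4899 and 5196 with IFNb.

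Libraries with p110 against panKO also held fewer interferon transcripts under PBS: 42 of 46 fell (42 adjusted over the list alone; median -1.53; adjusted p = 1.02e-32), with Apol9a at -5.68 ± 0.126, Iigp1 at -5.32 ± 0.24, Apol9b at -5.27 ± 0.126 and Slfn8 at -4.29 ± 0.195. With IFNb 27 fell and 5 rose (30 and 6; median -0.21; adjusted p = 9.97e-06). The T cell attractant Ccl5 stood at -1.69 ± 0.128, Nell2 at -2.51 ± 0.302, the aminopeptidase Anpep at -1.66 ± 0.172 and the receptor tyrosine kinase Kit at -1.62 ± 0.223. Cell cycle genes fell in 29 of 32 with IFNb (29; median -0.25; adjusted p = 3.6e-17), among them cyclin Ccne1 (-0.82 ± 0.0761). Ndrg2, Selenbp1, Rgs11 and Mgarp rose by 2.48 ± 0.148, 2.26 ± 0.0587, 2.17 ± 0.222 and 2.16 ± 0.102 under PBS. With IFNb, Tshz2, Apol10b, Fmo5 and Zfp980 rose by 2.49 ± 0.397, 1.65 ± 0.291, 1.52 ± 0.285 and 1.51 ± 0.267. Under PBS the panKO libraries detected 22670 and 22821 genes and those with p110 20836 and 21172, while with IFNb both are among the 6 that detected more. Calls came to 3618 up and 3600 down under PBS and 2281 and 2013 with IFNb. The IFNb count was 2833 without panKO IFNb replicate 1.

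The Zα-mutant p150 was compared with p150, the mouse counterpart of the N173S question. Stress genes were higher with the mutant: 24 of 25 integrated stress response genes rose under PBS (24 adjusted over the list alone; median 1.40; camera adjusted p = 7.11e-26) and 23 with IFNb (23; median 0.89; adjusted p = 5.08e-28). The transcription factors Cebpb and Atf3 rose by 2.64 ± 0.197 and 2.36 ± 0.093 under PBS, and Chac1 and the pseudokinase Trib3, both ATF4 and CHOP targets, by 2.11 ± 0.0697 and 2.09 ± 0.0519 with IFNb. Interferon-stimulated genes rose in 26 of 46 under PBS and fell in 1 (27 and 1; median 0.34; adjusted p = 7.34e-08), with Ddx60 up by 1.44 ± 0.154 and the dsRNA sensor regulator Dhx58 by 1.09 ± 0.171. With IFNb 10 rose and 10 fell (10 and 11; median -0.0027; adjusted p = 0.811), with Ifi211 up by 2.18 ± 0.247 and the GTPase Irgm1 at -0.63 ± 0.0476. Cell cycle genes fell in 23 of 32 under PBS and 23 with IFNb (23 and 24; adjusted p = 1.77e-07 and 2.36e-06), with Ccne2 at -0.91 ± 0.0905 and -0.68 ± 0.0815. The guanine exchange factor Rapgef5 changed by -3.90 ± 0.322 and -2.57 ± 0.263, Tinagl1 by -2.90 ± 0.126 and -2.61 ± 0.118 and the potassium channel Kcnj13 by -2.75 ± 0.158 and -2.25 ± 0.136. The cholesterol enzyme Mvd changed by -2.53 ± 0.113 under PBS and Adam12 by -2.97 ± 0.153 with IFNb. Creb5 and Cyb5r2 rose by 2.93 ± 0.253 and 2.71 ± 0.106 under PBS, and the thioredoxin inhibitor Txnip by 2.12 ± 0.047 with IFNb. Rps12-ps9, a pseudogene whose reads could be those of its parent, rose by 3.09 ± 0.943 but had an adjusted p of 0.107 to 0.805 without panKO_ZaMUTp150 PBS replicate 1, panKO_p150 PBS replicate 1 or panKO_p150 PBS replicate 2. Calls came to 3094 up and 3183 down under PBS and 2318 and 2541 with IFNb.

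The 2 isoforms were then compared directly, p110 against p150, with the same p150 libraries that served as reference for ZaMUTp150. Interferon genes were higher with p110: 44 of 46 under PBS (44 adjusted over the list alone; median 1.32, or 1.27 with genes at 0 counts at their bound; adjusted p = 1.4e-28) and 39 with IFNb, where 2 were lower (39 and 3; median 0.61; adjusted p = 1.54e-08). Usp18, a negative regulator of interferon signalling, rose by 2.54 ± 0.0841 and Oas2 by 2.43 ± 0.155 under PBS, and Stab2, Neurl3, Itgb8 and Oas3 by 6.73 ± 0.318, 5.39 ± 0.302, 4.04 ± 0.209 and 4.03 ± 0.312 with IFNb. Stress genes rose in 23 of 25 in both conditions (23 and 23; adjusted p = 1.62e-24 and 7.97e-12), with Cebpb up by 3.19 ± 0.182 under PBS and Atf3 by 2.31 ± 0.0927 and 3.73 ± 0.0725. Cell cycle genes fell in 23 of 32 under PBS and 31 with IFNb (23 and 31; adjusted p = 6.95e-10 and 9.75e-15), such as the mitotic kinase Aurkb (-1.48 ± 0.0571 with IFNb). Rapgef5, Cck, Tinagl1 and Adam12 changed by -3.63 ± 0.304, -2.78 ± 0.131, -2.31 ± 0.115 and -2.24 ± 0.146 under PBS. With IFNb, Smtnl2, Cck, Kcnj13 and Kbtbd11 changed by -4.77 ± 0.256, -4.69 ± 0.171, -3.63 ± 0.159 and -3.53 ± 0.0933, while Cyb5r2 rose by 2.44 ± 0.108 under PBS. The p110 libraries with IFNb are among the 6 that detected more genes, so this side of the comparison shares what set them apart. Calls came to 3034 up and 2931 down under PBS and 5444 and 5119 with IFNb.

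The last mouse comparison tested whether the answer to IFNb differed between genotypes. The rise of interferon-stimulated genes was smaller in panKO than in WT in 40 of 46 (40 adjusted over the list alone; median difference -2.05; adjusted p = 6.84e-44), with differences of -6.25 ± 0.273 for Apol9a, -5.78 ± 1.26 for Ifit1bl2 and -5.72 ± 0.179 for Oas2, genes already high in panKO under PBS, whose libraries enter both tests. Zbp1, also among the lowest, had no counts in WT under PBS and is given no difference. The response of Relb, a non-canonical NF-κB subunit, was larger by 1.86 ± 0.138, that of the collagen receptor Mrc2 by 1.93 ± 0.391 and that of H2-T24, one of the near-identical MHC genes, by 1.83 ± 0.365. The response of Plcl1 was larger by 1.67 ± 0.471, with an adjusted p of 0.0896 without WT PBS replicate 2. With ZaMUTp150 against p150, 18 interferon-stimulated genes had a smaller response (25; median -0.39; adjusted p = 4.6e-22), such as Mndal (-1.84 ± 0.394) and Ifit1 (-1.30 ± 0.0969), as had 15 of 25 stress genes (17; median -0.44; adjusted p = 2.33e-15), such as Cebpb (-1.45 ± 0.28). Cyb5r2 also responded less (-1.30 ± 0.156). The immediate early genes Fosb, Egr1 and Fos responded more (2.22 ± 0.268, 1.42 ± 0.147 and 1.27 ± 0.138), as did the chaperone partner Sdf2l1 (1.22 ± 0.113). With p110 against p150, 27 interferon-stimulated genes had a smaller and 7 a larger response (27 and 8; median -0.51; adjusted p = 0.00226), and 14 of 16 melanocyte genes a smaller one (14; median -0.66; adjusted p = 2.53e-07). H2-T24 and H2-K2 (3.94 ± 0.449 and 3.27 ± 0.278), von Willebrand factor Vwf (3.43 ± 0.272) and Cdhr2 (3.21 ± 0.388) responded more with p110. The response was smaller for Mgarp (-3.10 ± 0.149), Smtnl2 (-3.07 ± 0.355), Selenbp1 (-2.74 ± 0.081) and Rasd2 (-2.66 ± 0.193). The p110 response compares libraries that detected more genes, with IFNb, with p110 libraries that did not, under PBS, and the panKO libraries detected more in both treatments. Calls came to 1766 up and 2227 down for panKO, 208 and 258 for ZaMUTp150 and 3274 and 3858 for p110. The ZaMUTp150 count was 298 without panKO_ZaMUTp150 IFNb replicate 1 and 293 without panKO_p150 IFNb replicate 1.

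Other markers and the ADAR family were checked in each comparison. The checkpoint ligands and MHC class II list had 4 of 11 up and 4 down in panKO under PBS (4 and 4; adjusted p = 0.835). The cell death list had 14 up and 3 down of 22 (14 and 3; adjusted p = 0.00822). In the ADAR family, too small for camera, ADARB1 rose on average in N173S cells by 0.26 ± 0.0717 under PBS and 0.26 ± 0.0717 with IFNB. It lost these calls without any of 12 libraries (adjusted p = 0.0523 to 0.111) and of 8 libraries (0.0513 to 0.0806).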

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

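The tests of library size in both species, of a response to IFNb on its own, of libraries exchanged between lines, of edited against parental lines and of the differences between lines were chosen only after the results were seen, and those of dominant genes and genomic DNA before their own values but after the pattern was known.

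Several effects differed between groups when the difference itself was tested with edgeR. The response to IFNB differed between N173S and WT cells in 2 genes in HGC27, 2 in OE21 and 10 in OE33. In B16F10 the response to IFNb differed in 3993 genes between panKO and WT, in 466 between ZaMUTp150 and p150 and in 7132 between p110 and p150. Between the 4 human lines, the effect of IFNB differed in 206 genes in WT cells and 554 in N173S cells. The N173S effect with IFNB differed between lines in 2719 genes, and the response difference in 20.

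The N173S effect under PBS differed between lines in 3734 genes, of 20473. Libraries exchanged between lines are argued against, since 32 of 32 human libraries correlated best with the WT mean of their own line. For 4 counts of the average over the lines, the real labels alone, 1 of 25 splits, reached 1141 genes under PBS (highest other split 296), 1745 with IFNB (365), 764 for IFNB in WT cells (104) and 824 in N173S cells (64). Many redrawn groups mix genotypes or treatments, which widens the spread within a group and lowers the counts. Any steady difference between the cultures would give this, so the splits do not show an effect of the edit or one shared by the lines. With lines as replicates, limma called 0 genes for the genotype under PBS and 0 with IFNB. For the response difference the real labels called 0 genes, a count that all 25 of 25 splits reach by construction, so the splits say nothing about chance there. The highest called 658 (median 0), which points to a structure of the samples in that split, whose origin was not tested. Each line had 1 edited line, so differences between an edited clone and its parental line that do not come from the edit may account for the 3734 genes, and they cannot be told apart from the edit.

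In B16F10, the 6 libraries of panKO, and of p110 with IFNb, held counts for more genes than the other 14. With every library thinned to 15549365 counts the lowest of the 6 still exceeded the highest of the 14 by 1826 genes, and by 1607 without the 500 genes with the most counts, which argues against library size and against dominant genes as the whole cause. A response to IFNb on its own is argued against by WT cells, where IFNb added 161.5 genes, while panKO added 2210 under PBS. Genomic DNA in the RNA may be a source, since 122 of 2002 olfactory and vomeronasal receptor genes had a count on average in the 6 libraries and 51.2 in the 14 (lowest 88, highest 64), although wider transcription would give this too. The loss of ADAR1 that the labels name stays open beside it, as untested.

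In CAL27, N173S PBS replicate 1 and WT IFNB replicate 2 stood apart from their replicates. Swapped labels are argued against by the interferon-stimulated genes, whose median was 5.26 log2 CPM in N173S PBS replicate 1, 5.36 in its replicate and 8.68 to 9.01 in the IFNB libraries. Library size is argued against as well, since both held 22.9 M counts and the other 6 from 22.4 to 24.4. A trend on GC content and length removed 42.5% and 52.1% of the variance of the gene-wise deviation between replicates, against 17% and 21.8% in the other 2 pairs, so such a bias may account for part of it. The limit set for it, which both had to reach, was reached by WT IFNB alone, and the deviation is the same for both members of a pair. It cannot be told apart from a difference between the cultures, and no biological explanation was tested.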

How the results depend on the processing

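The tests without the 2 CAL27 libraries, and those named below as added, were chosen only after the results were seen; the other alternatives were fixed together with the gene lists and the rule for named genes. Over 69 settings, 2560 results were computed again. Of 585 counts of called genes 418 stayed within 1.5 times their value and 167 moved further; of 16637 values of single genes 14999 kept their direction and call, 1635 kept the direction alone and 3 turned; of 6581 list tests 6270 kept direction and call, 211 lost their call, 92 gained one and 8 turned. DESeq2 size factors kept 43 of 43 counts within 1.5 times. The same held for 35 with DESeq2, 41 with a minimum count of 50, 28 with no filter on low counts, 34 with the replicate number as a block, 23 of 34 with the groups of the contrast alone, 6 of 20 with all 32 human libraries, and 191 of 276 with 1 library left out. For counts that moved, the cause was not tested except where libraries or lines were left out. With 2 libraries per group, simulated recovery was 0% in CAL27, although it had the most counts, and what set it was not tested.

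With no filter on low counts, the counts were in HGC27 8 for the response difference, in OE21 202 for IFNB in WT cells, 901 for IFNB in N173S cells and 75 for the response difference, in OE33 1655 for the genotype under PBS, 1893 for the genotype with IFNB, 292 for IFNB in WT cells, 440 for IFNB in N173S cells and 56 for the response difference, in CAL27 341 for the genotype under PBS, 325 for the genotype with IFNB, 569 for IFNB in WT cells, 2743 for IFNB in N173S cells and 222 for the response difference, and on average 7 for the response difference. A minimum count of 50 gave 0 in OE21 and 5 in OE33 for the response difference. DESeq2 gave 19 in OE21 and 33 in OE33 for the response difference, in CAL27 193 for the genotype under PBS, 239 for the genotype with IFNB, 459 for IFNB in WT cells and 790 for IFNB in N173S cells, and on average 1756 for the genotype under PBS and 1260 for IFNB in N173S cells. With the groups of the contrast alone, the counts were in OE21 2364 for the genotype with IFNB, 293 for IFNB in WT cells and 105 for IFNB in N173S cells, in OE33 3017 for the genotype under PBS, 253 for the genotype with IFNB, 1832 for IFNB in WT cells and 115 for IFNB in N173S cells, in CAL27 0 for the genotype under PBS, 0 for the genotype with IFNB and 62 for IFNB in WT cells, and in B16F10 599 for IFNb in WT cells. All 32 human libraries in 1 fit gave in HGC27 661 for the genotype under PBS, 779 for the genotype with IFNB, 151 for IFNB in WT cells, 140 for IFNB in N173S cells and 0 for the response difference, in OE21 3757 for the genotype under PBS, 2351 for the genotype with IFNB and 139 for IFNB in N173S cells, in OE33 20 for the response difference, and in CAL27 786 for the genotype under PBS, 890 for the genotype with IFNB, 1374 for IFNB in WT cells, 5636 for IFNB in N173S cells and 2 for the response difference.

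Without OE21 the counts were on average 335 for the genotype under PBS and 733 for the genotype with IFNB. Without OE33 they were on average 497 for IFNB in WT cells, 540 for IFNB in N173S cells and 1 for the response difference, and without CAL27 on average 3920 for the genotype under PBS, 3263 for the genotype with IFNB, 409 for IFNB in WT cells, 497 for IFNB in N173S cells and 1 for the response difference. limma on the per-line changes gave on average 0 for the genotype under PBS, 0 for the genotype with IFNB, 32 for IFNB in WT cells and 3 for IFNB in N173S cells. Without the 2 CAL27 libraries that stand apart, the counts were in CAL27 964 for the genotype under PBS, 1581 for the genotype with IFNB, 5538 for IFNB in WT cells, 3937 for IFNB in N173S cells and 22 for the response difference, and on average 2855 for the genotype under PBS, 1899 for IFNB in WT cells, 1351 for IFNB in N173S cells and 1 for the response difference.

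With 1 library left out, which also leaves fewer samples, the counts ran in HGC27 from 1707 to 2600 for the genotype under PBS, 2367 to 3616 for the genotype with IFNB, 198 to 317 for IFNB in WT cells, 188 to 320 for IFNB in N173S cells and 1 to 3 for the response difference. In OE21 they ran from 3732 to 4290 for the genotype under PBS, 1840 to 7559 for the genotype with IFNB, 88 to 99 for IFNB in WT cells, 89 to 5609 for IFNB in N173S cells and 0 to 3950 for the response difference. OE33 gave 270 to 343 for the genotype under PBS, 259 to 5368 for the genotype with IFNB, 77 to 88 for IFNB in WT cells, 137 to 2250 for IFNB in N173S cells and 0 to 213 for the response difference. CAL27 gave 0 to 0 for the genotype under PBS, 0 to 6 for the genotype with IFNB, 33 to 250 for IFNB in WT cells and 42 to 100 for IFNB in N173S cells. The average gave 1068 to 4870 for the genotype with IFNB, 550 to 1215 for IFNB in WT cells, 585 to 1438 for IFNB in N173S cells and 0 to 1 for the response difference, and B16F10 gave 613 to 1120 for IFNb in WT cells, 1203 to 2167 for IFNb in p150 cells, 1295 to 1906 for IFNb in ZaMUTp150 cells, 2833 to 3358 for p110 against panKO with IFNb and 293 to 515 for the response of ZaMUTp150 against p150.

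Pairing of libraries by replicate number is not stated in the labels, and the main fits hold no block for it. Same-numbered libraries deviated from their group means with correlations from 0.044 to 0.227 in HGC27, -0.0343 to 0.305 in OE21, -0.365 to 0.596 in OE33, -0.89 to 0.572 in CAL27 and -0.0428 to 0.173 in B16F10. In HGC27 all were above 0, and in OE33 the highest was between N173S IFNB and N173S PBS. A shared replicate effect in some lines is therefore not excluded. The main HGC27 counts for IFNB were 380 in WT and 316 in N173S cells. With the replicate number as a block the counts were in HGC27 908 for IFNB in WT cells, 596 for IFNB in N173S cells and 10 for the response difference, in OE21 5 for the response difference, in OE33 4 for the response difference, and in CAL27 0 for the genotype under PBS, 0 for the genotype with IFNB, 113 for IFNB in WT cells and 74 for IFNB in N173S cells. The other 34 counts stayed within 1.5 times, as did all 5 counts of the average with a block of line by number. Of the list tests 1 lost and 1 gained a call under the block, and 39 values of named genes lost theirs.

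Turned values were as follows. Without HGC27 the mesenchymal list on average turned up under PBS (adjusted p = 0.142) and MLKL with IFNB stood at 0.027. Without OE21, MITF with IFNB stood at -0.027. Without OE33 the interferon-stimulated list turned up under PBS (adjusted p = 5.47e-08) and its response difference turned down (1.89e-20), the checkpoint and MHC class II list turned under PBS (0.685), and CD47 with IFNB stood at 0.024. Without CAL27 the cytokine list (0.515) and the NF-κB list (0.201) turned under PBS, the NF-κB list with IFNB (0.491), and the MHC class I response difference (0.00697). Without members that another list holds, the OE33 cytokine median with IFNB was 0.0092. With IFNB the median correlation of N173S changes was 0.158 at a log2 CPM of at least 3. For these values the cause was not tested, beyond the line or members left out. The limits used for untested values, 0.1 for a list median and a share of the range between pairs of lines for a correlation, were set by convention and not by replicate spread.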

Other observations

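The gene lists of this part, for cholesterol synthesis, mitochondrially encoded mRNAs, and aldo-keto reductases with NRF2 targets, and their camera tests, were chosen only after the results were seen, so the p values describe patterns already met and none is given where a list was chosen for the contrast; they are adjusted and use an estimated correlation.

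Genes of cholesterol synthesis differed between the genotypes of B16F10. All 23 fell with ZaMUTp150 against p150 under PBS (median -1.51) and 22 fell with IFNb (-0.83; adjusted p = 1.8e-05). With p110 against the same p150 libraries 23 of 23 fell under PBS (-1.32; adjusted p = 1.3e-05). Against panKO under PBS, p110 had 17 down and 1 up (-0.32; adjusted p = 0.00773). In panKO 21 exceeded WT under PBS (0.83; adjusted p = 0.000797). With IFNb 15 did and 4 were lower, without passing (0.38; adjusted p = 0.107). All 23 were higher in the same p150 PBS libraries than in panKO (0.84; adjusted p = 0.000155), so the p150 contrasts are not independent. IFNb raised 18 of the 23 in ZaMUTp150 cells and 2 in WT (0.44 and 0.07; adjusted p = 6.69e-05 and 0.0275). It lowered 23 in panKO, 20 in p110 and 13 in p150 cells (-0.42, -0.38 and -0.16; adjusted p = 0.000368, 0.0167 and 0.00354). The difference between the ZaMUTp150 and p150 responses was called in 19 (0.64; adjusted p = 2.94e-06). The libraries of panKO, and of p110 with IFNb, are the 6 that detected more genes. Of the 13 mitochondrially encoded mRNAs, IFNb lowered 7 in WT (-0.62). It lowered 11 with p150, 7 with ZaMUTp150, 13 with p110 and 7 in panKO (-0.84, -0.64, -1.17 and -0.49; adjusted p = 0.0153, 0.0218, 0.0838 and 0.114). None of the 3 differences in response passed for this list (adjusted p from 0.277 to 0.985).

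In the human lines, OE33 N173S cells held more of the aldo-keto reductase and NRF2 list, which covers detoxifying and glutathione genes: 10 of 21 rose under PBS (median 0.83) and 10 with IFNB (0.85), the near-identical AKR1C genes that prompted the list among them. In OE21 N173S cells 11 of 21 fell and 5 rose under PBS (-0.30; adjusted p = 0.139) and 10 fell and 4 rose with IFNB (-0.28; adjusted p = 0.107). In HGC27 N173S cells 8 of 19 tested members fell and 2 rose under PBS (-0.23; adjusted p = 0.0837). Cholesterol synthesis fell in HGC27 N173S cells, with 11 of 22 genes down under PBS (-0.28; adjusted p = 0.023) and 13 with IFNB (-0.28; adjusted p = 0.0151). The list also passed in OE33 N173S cells under PBS (3 of 23 down; -0.22; adjusted p = 0.016) and in CAL27 N173S cells with IFNB (0 called; -0.41; adjusted p = 0.032), but not in OE33 with IFNB (0.32), CAL27 under PBS (0.532) or OE21 (0.276 under PBS and 0.484 with IFNB).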
